A study of Mus musculus with 9 samples.

How the data were processed

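The values used are log2 signals per probe set, which the authors made with RMA (robust multi-array average) as named in the submitters' processing notes; software and version are not given in the sources used here. The deposited table holds 45101 probe sets for 9 arrays, and its probe set IDs are those of an Affymetrix whole-genome mouse expression array. T cells were taken after 24 h of culture, at 20 T cells per dendritic cell or with 0.1 µg/ml of each antibody, and crosslinked with 400 mJ/cm2 of ultraviolet light as the first dose before AGO immunoprecipitation. Array medians ran from 4.58 to 5.67 (log2), and the values were used as deposited, without a further normalization. The exact equality of 20.9% to 51.3% of values between arrays of 1 replicate number, and 0% between numbers, bears on how they were normalized and is weighed in the additional observations. For a single gene, equal signals within a number can be such exactly equal values and need not be a measured lack of change. No scanner files and no arrays of input RNA were used here.

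Control probe sets (64) were left out, as were 932 probe sets listed for several genes and 9160 with no gene listed. The other 34945 probe sets were given gene symbols from the platform annotation, with 34741 symbols brought up to date by gene ID from a mouse gene table. Each of 18193 genes was represented by its probe set with the highest mean over all 9 arrays, a choice that mattered for the 9010 genes with more than 1 probe set. Genome positions were not analysed here.

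Differences were tested with limma 3.58.1 in R 4.3.3 (linear model with 1 mean per group, moderated t-test with an intensity trend), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. All 9 arrays shared 1 estimate of spread. The moderated test had a median of 12.8 total degrees of freedom (residual plus prior), or 5.35 with the replicate block. The median SE of a log2 difference was 0.639, or 0.156 with the block, and the median log2 difference of all genes was 0.03, 0.00 and 0.04 in the 3 comparisons. Comparisons were allogeneic against syngeneic, anti-CD3/CD28 against syngeneic and allogeneic against anti-CD3/CD28. A gene was taken to set allogeneic culture apart when it passed both tests that involve the allogeneic arrays in the same direction. The correlation of the 2 effects against syngeneic culture was set beside 100 simulations of unchanged groups that share their controls.

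The replicate numbers pair the arrays: after removal of group means, correlations were 0.790 to 0.913 for the 9 pairs with the same number and −0.569 to −0.248 for the 18 pairs that differ in both number and group. Pairs of 1 group were left out, since removal of the group mean sets their deviations against each other. The 18 negative values are no separate evidence. Deviations cancel within each group, so high values for the same number force the others down. The test without a replicate block was fixed as the main test and the block as an alternative before the data were examined, together with the gene lists, the other alternatives and the rule for naming genes. Differences and list means are the same with and without the block, and only their errors and p-values change.

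In all, 35 gene lists with 707 genes were fixed, of which 630 genes were measured, and the 34 lists with at least 4 measured genes were tested. They cover T cell programmes, metabolism, ribosomes, cell division, cohesin, phosphoinositide phosphatases, the microRNA pathway, reported microRNA targets, stress responses and markers of other cell types. Lists were tested with limma's camera with a preset correlation of 0.01, with adjustment over the lists, and again with a correlation estimated from the data. Camera compares the test statistics of a list with those of all other genes. A shift means the mean log2 difference of the list minus that of other genes. The mean, the median and the camera direction of a list differed in sign for 7, 5 and 9 uncalled lists in the 3 comparisons and for 0 called lists. With the rotation test fry and the replicate block, the smallest adjusted p over lists was 0.111, 0.0220 and 0.896.

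Named genes follow a fixed rule: the 10 called genes with the largest rise or fall whose groups do not overlap or, where none was called, the 5 with the smallest p in each direction, predicted genes not named. To these come up to 4 members of each list with the smallest p, and Wapl, Synj1 and H2-Ea always. Single values chosen after they were seen are given beside such genes. The test was checked on simulated data, made once for each comparison. In each, 200 of 18193 genes were changed and a list of 25 other genes was shifted by 0.5 (log2). No unchanged gene was called without the block, and 10 were called with it in each simulation.

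Alternatives were the replicate block, quantile normalization, arrays centred on their medians, dim genes left out (40th percentile), other variance priors, array weights, only the groups compared, the mean of a gene's probe sets, cross-hybridising probe sets left out, every probe set tested, a change of at least 1 on the log2 scale and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.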

Results

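The samples were mouse T cells, and the measurement was RNA recovered with Argonaute (AGO), the protein that carries microRNAs and holds the transcripts they pair with. C57BL/6 T cells were kept for 24 h with dendritic cells of their own strain (syngeneic) or with dendritic cells from BALB/c mice (allogeneic). Others were kept for 24 h with antibodies to CD3e and CD28 at 0.1 µg/ml. These antibodies drive the T cell receptor and a co-stimulatory receptor without antigen. Dendritic cells were present at 1 per 20 T cells in the co-cultures, and none are named for the antibody culture. T cells were then purified on magnetic columns, crosslinked with ultraviolet light and lysed, AGO was immunoprecipitated, and the recovered RNA was amplified and hybridised to 1 expression array per sample. Each of the 3 groups had 3 arrays, which the labels number as biological replicates 1 to 3 without naming animals or cultures. The p-values of single genes in limma thus measure the spread between these 9 arrays. The p-values of gene lists in camera with the preset correlation compare the genes of a list with all other genes. Those list p-values depend mainly on the number and spread of genes, and are not a measure of replication across arrays. Values are log2 array signals of AGO-bound RNA for 18193 genes, with no matching arrays of input RNA analysed here, so transcript abundance and AGO binding are not separated. The number of arrays limits the precision of every value.

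Arrays with the same replicate number resembled each other more than arrays of the same group. Replicate number accounted for 85.3% of the variance of the 9 arrays and group for 6.08%, where unrelated arrays would give 25% each. In number 1 the allogeneic and anti-CD3/CD28 arrays were close to identical: their difference had an SD of 0.103 (log2) across genes, against 0.422 between the allogeneic and syngeneic arrays of that number. The same SD between allogeneic and anti-CD3/CD28 arrays was 0.493 in number 2 and 0.680 in number 3. For each gene list below, 3 values in parentheses are the mean log2 differences within replicate numbers 1, 2 and 3, and adjusted p-values come from limma's camera test with a preset correlation unless an estimated correlation is named.

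**Figure D1:**
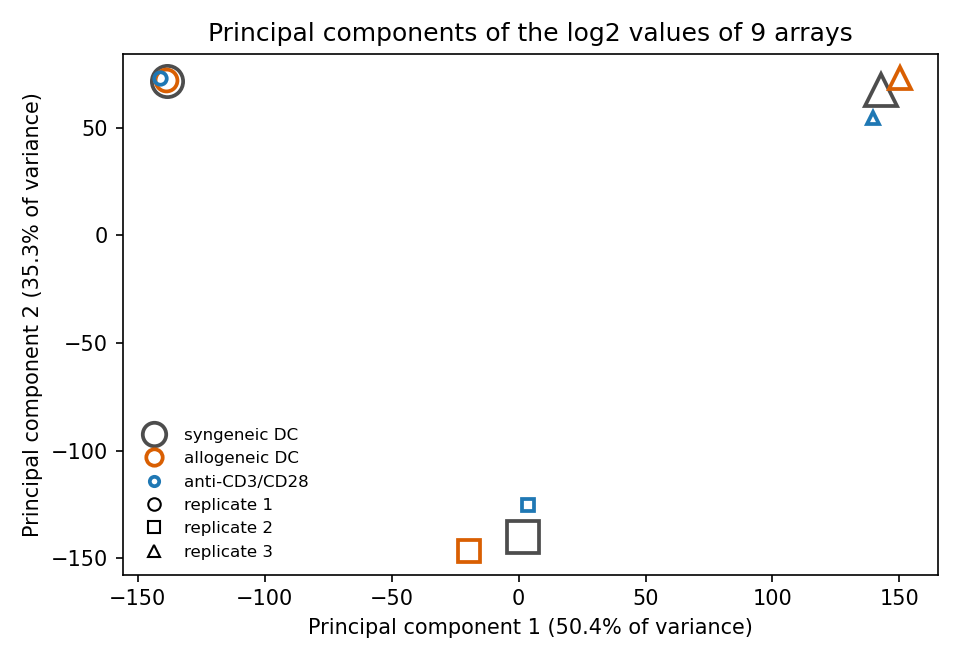
Principal components 1 and 2 (50.4% and 35.3% of the variance) of the log2 values of the 9 arrays, with marker shape for the replicate number and colour and marker size for the group. The arrays form 3 clusters by replicate number, each holding all 3 groups.

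Allogeneic against syngeneic co-culture asks which AGO-bound transcripts change when T cells meet dendritic cells of a foreign strain. The 15 macrophage and monocyte genes fell, with a mean log2 difference of −1.27 (−1.15, −1.45 and −1.22), and all 15 were lower. They had adjusted p = 3.12e-34 and kept their call at adjusted p = 0.0117 with an estimated correlation, though not with the replicate block and an estimated correlation together (adjusted p = 0.177). The 23 mitosis genes rose by a mean log2 difference of 0.81 (1.53, 0.07 and 0.83), 22 of them higher, with adjusted p = 1.45e-25, and adjusted p = 0.351 with an estimated correlation. Both lists were called in each of the 9 fits that left out 1 array.

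Among the macrophage and monocyte genes, Csf1r, the receptor for macrophage colony-stimulating factor, stood at 5.64 ± 1.15 (SD, n = 3) after allogeneic and 9.30 ± 0.64 after syngeneic culture, a log2 difference of −3.67 ± 0.74 (SE). The phagocyte lysozymes Lyz1 and Lyz2 differed by −2.70 ± 0.64 and −2.59 ± 0.63. These 3 genes fell when adjusted over the list alone, and 6 did so with the replicate block, although 1 of the 3 probe sets of Csf1r and 1 of the 3 of Lyz1 did not share the sign. The complement gene C1qb differed by −2.46 ± 1.22 and was not called. Csf1r lay at or under the array median on 4 arrays and C1qb on 4, all of them from stimulated cultures, so the sizes of these falls are not exact. Among mitosis genes the cyclin-dependent kinase Cdk1 differed by 1.74 ± 0.74, the ubiquitin-conjugating enzyme Ube2c by 1.63 ± 0.91, the spindle motor Kif11 by 1.02 ± 0.58 and the cyclin Ccna2 by 1.18 ± 0.71, and no mitosis gene was called alone.

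Another 3 lists linked to growth rose as well. The 34 genes of DNA replication and G1/S rose (mean 0.48; 1.12, −0.19 and 0.50), with adjusted p = 4.34e-12, and adjusted p = 0.527 with an estimated correlation. Thymidine kinase Tk1 differed by 1.82 ± 0.88 and the replication helicase subunit Gins2 by 1.43 ± 0.80. Tk1 lay under the array median on syngeneic replicates 1 and 2, so the size of its difference is not exact. The call of the list ended without allogeneic replicate 3 (adjusted p = 0.251). The 25 ribosome biogenesis genes rose (mean 0.37; 0.45, −0.04 and 0.70), 23 of them higher, with adjusted p = 3.21e-09, and adjusted p = 0.527 with an estimated correlation. That call ended without syngeneic replicate 2 or allogeneic replicate 3 (adjusted p up to 0.448). Nop58, a core protein of small nucleolar RNA complexes, differed by 0.81 ± 0.40, and Gar1 by 0.74 ± 0.53. The 42 cytosolic ribosomal protein genes rose slightly (mean 0.12; 0.20, 0.16 and 0.01), with adjusted p = 0.0125, and adjusted p = 0.963 with an estimated correlation. Without syngeneic replicate 2 or allogeneic replicate 1 this list was called in the other direction (shift as low as −0.27), and without allogeneic replicate 3 it was not called (adjusted p up to 0.0987).

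Effector genes of T cells rose as a list in the allogeneic cultures. The 26 cytokine and cytotoxic genes had a mean log2 difference of 0.42 (0.42, −0.01 and 0.84), 15 of them higher, with adjusted p = 3.13e-06, and adjusted p = 0.870 with an estimated correlation. The call ended with the replicate block (adjusted p = 0.25), without syngeneic replicate 1 (adjusted p up to 0.618) and without allogeneic replicate 3, where the shift turned to −0.17. Gzmb, the granule protease of killer cells, stood at 10.72 ± 0.58 against 8.64 ± 1.66 and differed by 2.09 ± 0.71, with 4.07, 0.94 and 1.25 within the numbers. Il2, the T cell growth factor, differed by 2.08 ± 0.92. Il3 stood at 9.38 on allogeneic replicate 3 and between 3.82 and 4.85 on the other 8 arrays. The 29 T cell activation genes rose (mean 0.16; 0.54, −0.27 and 0.20), with adjusted p = 0.0259, and adjusted p = 0.963 with an estimated correlation. That call ended with the replicate block (adjusted p = 0.465) and without syngeneic replicate 1 or 2 or allogeneic replicate 1 or 3 (adjusted p up to 0.954, shift as low as −0.22). The amino acid transporter Slc7a5 differed by 1.12 ± 0.61, the transferrin receptor Tfrc by 0.75 ± 0.46, and Il2ra, the high-affinity subunit of the interleukin-2 receptor, by 0.66 ± 0.49.

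Smaller falls were called in 5 further lists. The 34 interferon response genes fell (mean −0.20; −0.40, 0.00 and −0.21), 28 of them lower, with adjusted p = 0.00508, and adjusted p = 0.963 with an estimated correlation. Rsad2 differed by −0.85 ± 0.72 and Ifit3 by −0.55 ± 0.53. The 23 genes of quiescence and the naive state fell (mean −0.17; −0.27, −0.14 and −0.09), with adjusted p = 0.0120, and adjusted p = 0.963 with an estimated correlation. Foxo1, a transcription factor of resting T cells, differed by −0.85 ± 0.57. The 10 reported miR-155 targets fell (mean −0.26; −0.39, −0.42 and 0.03), with adjusted p = 0.0259, and adjusted p = 0.870 with an estimated correlation. Bach1 differed by −1.22 ± 0.75 and Maf by −0.97 ± 0.85, both transcription factors. The 20 dendritic cell genes fell (mean −0.23; −0.02, −0.67 and 0.00), with adjusted p = 0.0259, and adjusted p = 0.963 with an estimated correlation. On its brightest probe set the class II gene H2-Ab1 differed by −0.99 ± 0.70, and its 2 other probe sets had no such fall. The 12 B cell genes fell (mean −0.24; −0.23, −0.38 and −0.12), with adjusted p = 0.0259, and adjusted p = 0.963 with an estimated correlation. The immunoglobulin heavy chain gene Ighm differed by −0.67 ± 0.48. Probe sets that shared the sign were 3 of 4 for Foxo1, 1 of 2 for Bach1, 5 of 6 for Maf and 9 of 11 for Ighm. The means of miR-155 targets, dendritic cell and B cell genes were lowest in number 2, as was that of macrophage and monocyte genes (−1.45). In number 2 the stromal genes Col1a2 and Col3a1 were lower as well, at 9.23 against 11.3 and 9.27 against 10.9. In numbers 1 and 3 both were equal in the 2 cultures, at or under the array median. None of these 5 calls held in every fit that left out 1 array. Syngeneic replicate 3 or allogeneic replicate 1 or 2 carried the interferon call (adjusted p up to 0.765), and syngeneic replicate 1 or 3 or allogeneic replicate 2 the quiescence call (adjusted p up to 0.964). For miR-155 targets the arrays were syngeneic replicates 1 and 3 and allogeneic replicates 1 and 2 (adjusted p up to 0.962), for dendritic cell genes syngeneic replicates 2 and 3 and allogeneic replicates 1 and 2 (adjusted p up to 0.995), and for B cell genes syngeneic replicates 2 and 3 and allogeneic replicates 1 and 3 (adjusted p up to 0.995). Of 10 alternatives to the scaling, the block, the filter or the spread, 4 ended the calls of quiescence and of T cell activation, 3 that of miR-155 targets, 2 each those of ribosomal protein, dendritic cell and B cell genes, and 1 each those of cytokines and of the interferon response (adjusted p up to 0.465). Without the arrays numbered 1, an alternative chosen after the data were seen, 7 of the 12 calls of this comparison ended, DNA replication among them (adjusted p = 0.438), and mitosis, ribosome biogenesis, cytokine, macrophage and dendritic cell lists were called.

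Gene by gene, limma called 0 of 18193 between allogeneic and syngeneic cultures, with or without a fixed replicate block, and 1 (Csf1r, adjusted p = 0.0143) with replicate number as a random block, an alternative chosen after the data were seen. At an unadjusted p under 0.05 there were 27 genes, 6 higher and 21 lower, where 909.65 would be expected by chance if the arrays were unpaired, and 825 with the block. The genes nearest to a call were Gzmb, Ppp5c (1.41 ± 0.58), Cdk1, Il2 and the small nucleolar RNA host gene Snhg3 (1.36 ± 0.61) on the higher side. On the lower side they were Csf1r, Lyz1, Lyz2, the macrophage lectin Chil3 (−2.18 ± 0.57) and the acute-phase gene Saa3 (−2.81 ± 0.81). Chil3 lay at or under the array median on 7 of the 9 arrays, so the size of its difference is not exact. In simulated data the unblocked test recovered 0% of genes changed by 2 on the log2 scale and 67.7% of those changed by 4. With the block it recovered 85.1% and 100%. The simulation gave each gene independent errors of 1 size on all arrays, unlike the real arrays. Hence 0 genes called with the block do not exclude large changes. In 117 genes (0.643%) the 3 arrays of the groups did not overlap, against 10% by chance for unpaired arrays.

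**Figure D2:**
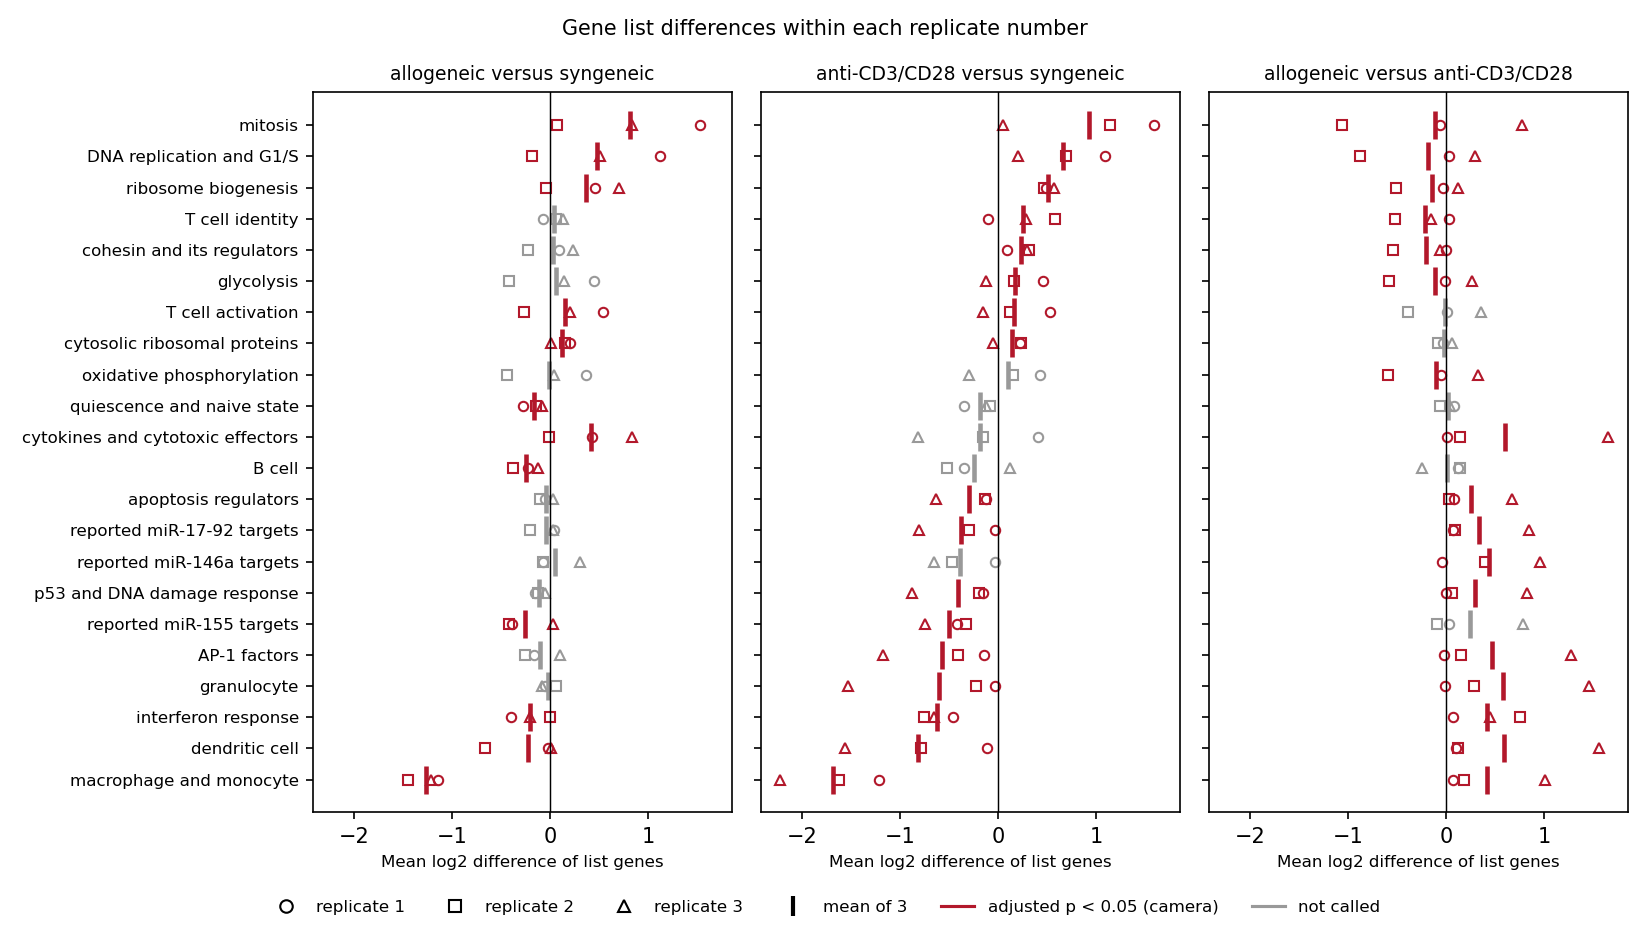
Mean log2 difference of the genes in each list (x axis) for 3 comparisons, with circles, squares and triangles for replicate numbers 1, 2 and 3 and a bar for their mean. Lists in red had an adjusted p under 0.05 in camera with a preset correlation, and lists in grey did not. Macrophage and monocyte genes lie below 0 in every number against syngeneic culture, between −1.15 and −1.45 for allogeneic and between −1.22 and −2.22 for anti-CD3/CD28.

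Anti-CD3/CD28 and syngeneic cultures differ both in the antibody stimulus and in the dendritic cells, which only the syngeneic culture is described to hold, and no test here separates the 2. Macrophage and monocyte genes fell, with a mean of −1.69 (−1.22, −1.63 and −2.22), all 15 lower. They had adjusted p = 3.44e-33 and kept their call at adjusted p = 0.0128 with an estimated correlation, though not with the replicate block as well (adjusted p = 0.157). The 20 dendritic cell genes fell, with a mean of −0.82 (−0.11, −0.79 and −1.56) and adjusted p = 1.98e-10, and adjusted p = 0.176 with an estimated correlation. The 23 mitosis genes rose by 0.93 (1.59, 1.14 and 0.05), all 23 higher, with adjusted p = 4.8e-24, and adjusted p = 0.176 with an estimated correlation. The 34 genes of DNA replication and G1/S rose by 0.66 (1.09, 0.69 and 0.21), 31 of them higher, with adjusted p = 1.2e-19, and adjusted p = 0.176 with an estimated correlation. The 25 ribosome biogenesis genes rose by 0.51 (0.49, 0.47 and 0.57), all 25 higher, with adjusted p = 6.96e-14, and adjusted p = 0.176 with an estimated correlation. These 5 lists were called in each of the 9 fits that left out 1 array.

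Among macrophage and monocyte genes Lyz2 stood at 7.56 ± 1.07 (SD, n = 3) after anti-CD3/CD28 and 11.64 ± 0.89 after syngeneic culture, a log2 difference of −4.08 ± 0.63 (SE). Csf1r differed by −4.60 ± 0.74 and Lyz1 by −3.95 ± 0.64, each with 2 of 3 probe sets sharing the sign. These 3 fell when adjusted over the list alone, 6 members did so with the replicate block, and over all genes their adjusted p was 0.227 each. The dendritic cell chemokine genes Ccl17 and Ccl22 differed by −3.13 ± 0.92 and −1.43 ± 0.45, and Fscn1, the actin-bundling protein of mature dendritic cells, by −2.28 ± 0.76. Ccl17 stood at 9.80 in both cultures in number 1, and at 7.53 against 10.93 and 5.86 against 11.87 in numbers 2 and 3. Among proliferation genes Cdk1 differed by 1.92 ± 0.74, Kif20a by 1.23 ± 0.58, the ribonucleotide reductase gene Rrm1 by 1.24 ± 0.53, the replication licensing gene Mcm3 by 1.13 ± 0.62 and Nop58 by 1.10 ± 0.40. With the replicate block, 3 ribosome biogenesis genes rose when adjusted over the list alone, against 0 without it.

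Interferon response genes fell in the antibody cultures relative to syngeneic culture. The 34 genes had a mean log2 difference of −0.63 (−0.47, −0.76 and −0.65), 26 of them lower, with adjusted p = 2.18e-09, and adjusted p = 0.336 with an estimated correlation. Without syngeneic replicate 3 the call ended (adjusted p = 0.0987), and with the replicate block it held in all 9 such fits. Rsad2 differed by −1.97 ± 0.72, Ifit3 by −1.23 ± 0.53, Mx1 by −1.37 ± 0.62 and Ifit1 by −1.74 ± 0.91, all antiviral genes induced by interferon. The 12 AP-1 factors fell as well (mean −0.57; −0.14, −0.41 and −1.18), 11 of them lower, with adjusted p = 0.000160, and adjusted p = 0.336 with an estimated correlation. Fosl2 differed by −2.15 ± 0.67 and Jun by −1.26 ± 0.63, and the call ended without syngeneic replicate 3 (adjusted p = 0.235). The 10 granulocyte genes fell (mean −0.60; −0.04, −0.23 and −1.54), with adjusted p = 0.00458, and adjusted p = 0.336 with an estimated correlation. S100a9 differed by −2.10 ± 1.16 and S100a8 by −1.79 ± 0.98. The size for S100a9 is not exact, as it lay under the array median on anti-CD3/CD28 replicate 3. The granulocyte call ended with the replicate block (adjusted p = 0.301) and without syngeneic replicate 2 or 3 or anti-CD3/CD28 replicate 3 (adjusted p up to 0.363). AP-1 factors had their lowest mean in number 3, as did dendritic cell, granulocyte and macrophage genes.

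T cell identity and activation lists rose in the antibody cultures. The 23 T cell identity genes rose (mean 0.26; −0.10, 0.58 and 0.29), with adjusted p = 0.000573, and adjusted p = 0.632 with an estimated correlation. Cd8b1 differed by 0.94 ± 0.65 and the co-stimulatory receptor Cd28 by 0.74 ± 0.61. The call ended without syngeneic replicate 2, where the shift was −0.14, and without anti-CD3/CD28 replicate 3 (adjusted p up to 0.843). The 29 T cell activation genes rose (mean 0.16; 0.53, 0.12 and −0.16), with adjusted p = 0.00458, and adjusted p = 0.660 with an estimated correlation. Tfrc differed by 1.02 ± 0.46, and Nr4a1, an early gene of receptor signalling, by 1.45 ± 0.78. The call ended with the replicate block (adjusted p = 0.104) and without syngeneic replicate 1 or 2 or anti-CD3/CD28 replicate 3 (adjusted p up to 0.955, shift as low as −0.03). The 18 glycolysis genes rose (mean 0.17; 0.46, 0.17 and −0.12), with adjusted p = 0.00502, and adjusted p = 0.660 with an estimated correlation. Ldha differed by 0.56 ± 0.42 and the lactate transporter Slc16a1 by 0.80 ± 0.53, while the regulatory gene Pfkfb3 differed by −1.52 ± 0.73. That call ended without syngeneic replicate 1 or 2 or anti-CD3/CD28 replicate 3 (adjusted p up to 0.814) and with arrays centred on their medians (adjusted p = 0.0704). The 42 cytosolic ribosomal protein genes rose (mean 0.14; 0.23, 0.24 and −0.05), with adjusted p = 0.00113, and adjusted p = 0.685 with an estimated correlation, and were called in the other direction without syngeneic replicate 2 or anti-CD3/CD28 replicate 1 (shift as low as −0.18). The 17 genes of cohesin and its regulators, a group that holds Wapl, rose (mean 0.23; 0.09, 0.31 and 0.29), with adjusted p = 0.0395, and adjusted p = 0.660 with an estimated correlation. Espl1, the separase that opens cohesin, differed by 1.18 ± 0.69 and its inhibitor Pttg1 by −0.58 ± 0.46. The cohesin call ended with the replicate block (adjusted p = 0.240) and without syngeneic replicate 1 or 2 or anti-CD3/CD28 replicate 3 (adjusted p up to 0.800).

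Of the 5 lists of reported microRNA targets 2 fell in the antibody cultures, as did p53 and apoptosis genes. The 10 reported miR-155 targets fell (mean −0.50; −0.42, −0.33 and −0.75), 8 of them lower, with adjusted p = 0.00157, and adjusted p = 0.336 with an estimated correlation. Cebpb differed by −1.37 ± 0.70 and Maf by −1.54 ± 0.85, with 1 of 2 and 5 of 6 probe sets sharing the sign. Of these 10 genes, Cebpb and Spi1 are also transcription factors of myeloid cells, and the 8 others had adjusted p = 0.0395 at the preset correlation. The 8 others still include Maf, and whether they are free of signal from myeloid cells was not tested. The miR-155 call ended without syngeneic replicate 3 or anti-CD3/CD28 replicate 2 (adjusted p up to 0.329). The 11 reported miR-17 cluster targets fell (mean −0.38; −0.03, −0.30 and −0.81), with adjusted p = 0.0123, and adjusted p = 0.494 with an estimated correlation. Ikzf4 differed by −1.14 ± 0.47 and the cell cycle inhibitor Cdkn1a by −1.73 ± 1.01. The 21 genes of p53 and the DNA damage response fell (mean −0.41; −0.15, −0.19 and −0.88), with adjusted p = 0.00458, and adjusted p = 0.458 with an estimated correlation. Gadd45g differed by −1.04 ± 0.67. The 19 apoptosis regulators fell (mean −0.30; −0.13, −0.13 and −0.64), with adjusted p = 0.0159, and adjusted p = 0.605 with an estimated correlation. Birc2, an inhibitor of apoptosis, differed by −0.91 ± 0.43. These 4 lists had their lowest means in number 3, where those of dendritic cell (−1.56), granulocyte (−1.54) and macrophage genes (−2.22) were lowest too. With the replicate block the miR-17 cluster (adjusted p = 0.108) and apoptosis lists (adjusted p = 0.0673) were not called. Each of the miR-17 cluster, p53 and apoptosis calls ended without syngeneic replicate 3 or anti-CD3/CD28 replicate 1 or 2, and the apoptosis call also without syngeneic replicate 2 (adjusted p up to 0.772, 0.642 and 0.732). Of the 10 alternatives 4 ended the apoptosis and cohesin calls, 3 the miR-17 cluster call and 1 each the T cell activation, glycolysis and granulocyte calls (adjusted p up to 0.301). Without the arrays numbered 1 the T cell activation, glycolysis and ribosomal protein calls ended (adjusted p = 0.530, 0.283 and 0.0709).

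Between anti-CD3/CD28 and syngeneic cultures limma called 0 of 18193 genes, and 0 with a fixed replicate block. It called 30 with replicate number as a random block (smallest adjusted p 0.00146, Csf1r) and 1 with arrays centred on their medians (adjusted p = 0.0485). At an unadjusted p under 0.05 there were 156 genes, 15 higher and 141 lower, and 1236 with the block. The genes nearest to a call on the higher side were Gzmb (2.19 ± 0.71), Nop58, Snhg3 (1.66 ± 0.61), the condensin gene Ncapg (1.4995 ± 0.58) and Cdk1. On the lower side they were Lyz2, Csf1r, Lyz1, Saa3 (−4.15 ± 0.81) and Tnfaip2 (−3.56 ± 0.74). Saa3 lay under the array median on anti-CD3/CD28 replicates 2 and 3, so the size of its difference is not exact. With the same limit, simulated genes changed by 2 and by 4 on the log2 scale were recovered at 3.45% and 69.7%, against 87.9% and 100% with the block. The 3 arrays of the groups did not overlap in 351 genes (1.93%), against 10% by chance for unpaired arrays.

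Allogeneic and anti-CD3/CD28 cultures differ in the stimulus and in the presence of dendritic cells. Of 34 lists 17 were called, 10 higher and 7 lower after allogeneic culture, and 0 with an estimated correlation (smallest adjusted p 0.317). The 26 cytokine and cytotoxic genes rose by a mean of 0.60 (0.01, 0.14 and 1.66), 22 of them higher, with adjusted p = 6.83e-11, and adjusted p = 0.427 with an estimated correlation. The 20 dendritic cell genes rose by 0.59 (0.10, 0.12 and 1.56), with adjusted p = 2.43e-09, and adjusted p = 0.317 with an estimated correlation. Without allogeneic replicate 3 both calls ended, with adjusted p up to 0.875 and a cytokine shift of −0.05, and adjusted p up to 0.635 for dendritic cell genes. The dendritic cell call also ended with the replicate block (adjusted p = 0.0590). In number 3 the dendritic cell genes had a mean difference from syngeneic culture of 0.00 after allogeneic culture and −1.56 after anti-CD3/CD28.

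Il21, a cytokine that helps B cells, stood at 5.48 ± 1.13 (SD, n = 3) after allogeneic culture and 4.06 ± 0.62 after anti-CD3/CD28, a log2 difference of 1.42 ± 0.63 (SE). On 8 of the 9 arrays Il21 lay at or under the array median, so its difference is measured against low signal and its size is not exact. The granzyme gene Gzma differed by 1.54 ± 0.77, the chemokine gene Ccl5 by 1.12 ± 0.71 and Il2 by 1.45 ± 0.92. In the dendritic cell list Ccl17 differed by 2.94 ± 0.92 (0.21, 2.29 and 6.30 within the numbers), Fscn1 by 2.21 ± 0.76, Ccl22 by 1.25 ± 0.45 and the co-stimulatory ligand Cd86 by 1.55 ± 1.03. The 15 macrophage and monocyte genes rose (mean 0.42; 0.07, 0.18 and 1.01), with adjusted p = 4.01e-06, and adjusted p = 0.317 with an estimated correlation. Lyz2 differed by 1.496 ± 0.63. The 10 granulocyte genes rose (mean 0.58; −0.02, 0.29 and 1.46), with adjusted p = 2.87e-05, and adjusted p = 0.317 with an estimated correlation. S100a9 differed by 1.88 ± 1.16, with 5.50 in number 3. On anti-CD3/CD28 replicate 3 it lay under the array median (3.73 against 4.93), so these sizes are not exact. Both calls ended with the replicate block (adjusted p = 0.0604 and 0.113) and without anti-CD3/CD28 replicate 3 (adjusted p up to 0.138 and 0.242).

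The 34 interferon response genes rose (mean 0.42; 0.07, 0.76 and 0.44), 25 of them higher, with adjusted p = 1.56e-06, and adjusted p = 0.539 with an estimated correlation. Mx1 differed by 1.06 ± 0.62, Rsad2 by 1.12 ± 0.72 and the exonuclease gene Isg20 by 1.46 ± 1.10. The call ended without allogeneic replicate 3 or anti-CD3/CD28 replicate 1 or 2 (adjusted p up to 0.892), and with the replicate block it held in all 9 fits that left out 1 array. The 12 AP-1 factors rose (mean 0.47; −0.02, 0.15 and 1.27), with adjusted p = 7.77e-06, and adjusted p = 0.427 with an estimated correlation. Jun differed by 1.18 ± 0.63, and the call ended without allogeneic replicate 3 or anti-CD3/CD28 replicate 1 (adjusted p up to 0.951). Reported targets of miR-17 cluster rose in the same comparison (11 genes, mean 0.33; 0.07, 0.09 and 0.84), with adjusted p = 0.0160, and adjusted p = 0.539 with an estimated correlation. So did 5 reported miR-146a targets (mean 0.44; −0.04, 0.39 and 0.96), with adjusted p = 0.0488, and adjusted p = 0.682 with an estimated correlation. Ikzf4 differed by 1.02 ± 0.47 and Relb by 0.96 ± 1.08. The 21 genes of p53 and the DNA damage response rose (mean 0.29; 0.00, 0.06 and 0.82), with adjusted p = 0.0488, and adjusted p = 0.643 with an estimated correlation. The 19 apoptosis regulators rose (mean 0.26; 0.08, 0.02 and 0.67), with adjusted p = 0.0180, and adjusted p = 0.603 with an estimated correlation. Cdkn1a differed by 1.81 ± 1.01, with 4.51 in number 3, and Birc2 by 0.49 ± 0.43. AP-1 factors and these last 4 lists had their highest means in number 3, where those of dendritic cell (1.56), granulocyte (1.46) and macrophage genes (1.01) were highest too. With the replicate block none of the 4 was called (adjusted p = 0.298, 0.0604, 0.611 and 0.0604). All 4 calls also ended without allogeneic replicate 3 or anti-CD3/CD28 replicate 1 or 2, the miR-146a call without syngeneic replicate 2 and the apoptosis call without allogeneic replicate 2 (adjusted p up to 0.845, 0.758, 0.690 and 0.901).

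The 23 T cell identity genes fell (mean −0.22; 0.03, −0.52 and −0.16), 20 of them lower, with adjusted p = 4.01e-06, and adjusted p = 0.539 with an estimated correlation. Cd28 differed by −0.98 ± 0.61. The 34 genes of DNA replication and G1/S fell (mean −0.18; 0.03, −0.88 and 0.30), with adjusted p = 3.94e-06, and adjusted p = 0.539 with an estimated correlation. The 23 mitosis genes fell (mean −0.12; −0.06, −1.07 and 0.78), with adjusted p = 0.0223, and adjusted p = 0.755 with an estimated correlation, and were not called with the replicate block (adjusted p = 0.0688). Mcm3 differed by −0.93 ± 0.62 (−0.38, −1.99 and −0.43), and the kinetochore motor Cenpe by −1.30 ± 1.00, with −4.00 in number 2. The 25 ribosome biogenesis genes fell (mean −0.14; −0.03, −0.51 and 0.13), with adjusted p = 0.000309, and adjusted p = 0.539 with an estimated correlation. Falls were also called for 17 cohesin genes (mean −0.20; 0.00, −0.54 and −0.06), with adjusted p = 0.00106, and adjusted p = 0.539 with an estimated correlation. The 18 glycolysis genes fell (mean −0.11; −0.01, −0.58 and 0.26), with adjusted p = 0.00565, and adjusted p = 0.650 with an estimated correlation. The 35 oxidative phosphorylation genes fell (mean −0.11; −0.06, −0.59 and 0.33), with adjusted p = 0.00216, and adjusted p = 0.687 with an estimated correlation. Polr1a, a subunit of RNA polymerase I, differed by −0.54 ± 0.66 (4 of 5 probe sets lower), the cohesin subunit Smc1a by −0.64 ± 0.63, Pfkp by −0.57 ± 0.56 and Uqcrc2 by −0.59 ± 0.49. All 7 means were lowest in number 2, and each call ended or turned without allogeneic replicate 2, where the shifts reached 0.16 for T cell identity, 0.19 for DNA replication, 0.28 for mitosis, 0.23 for ribosome biogenesis, 0.23 for glycolysis and 0.28 for oxidative phosphorylation. Without anti-CD3/CD28 replicate 3 all but the oxidative phosphorylation call ended, as did the cohesin call without allogeneic replicate 1, the mitosis call without allogeneic replicate 1 or anti-CD3/CD28 replicate 1 or 2, and the ribosome biogenesis, glycolysis and oxidative phosphorylation calls without anti-CD3/CD28 replicate 1 (adjusted p up to 0.985 over these fits). Among all 17 lists called in this comparison, 6 of the 10 alternatives ended the call of miR-146a targets, 5 that of p53, 3 each those of miR-17 cluster targets and apoptosis, 2 each those of glycolysis and mitosis, and 1 each those of oxidative phosphorylation, dendritic cell, macrophage and granulocyte genes (adjusted p up to 0.611).

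Between allogeneic and anti-CD3/CD28 cultures limma called 0 of 18193 genes, and 0 with a fixed or a random replicate block. At an unadjusted p under 0.05 there were 24, of which 23 were higher after allogeneic culture, and 205 with the block. The genes nearest to a call on the higher side were Ccl17, the kinase inhibitor gene Pkib (2.76 ± 0.94), Fscn1, the protease inhibitor gene Cst3 (1.72 ± 0.60) and Igfbp4 (1.47 ± 0.52). Within number 1 these 5 differed by 0.21, −0.23, 0.48, 0.30 and 0.26. On the lower side they were Mical1 (−1.35 ± 0.53), the actin-bundling gene Lcp1 (−0.70 ± 0.32), the non-muscle myosin gene Myh9 (−0.78 ± 0.37), Mfsd4a (−1.33 ± 0.66, with 3 of its 4 probe sets sharing the sign) and Svil (−2.03 ± 1.01). With the same limit, simulated genes changed by 2 and by 4 on the log2 scale were recovered at 1.25% and 60.3%, against 90% and 98.3% with the block. Groups did not overlap in 59 genes (0.324%), against 10% by chance for unpaired arrays.

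A gene particular to allogeneic activation would have to differ from both other groups in the same direction. No gene passed both tests in limma (0 at an unadjusted p under 0.05 in both), and with the replicate block 0 passed and 26 did so unadjusted, 19 of them higher. Across 18193 genes, which are not independent replicates, the log2 differences of the 2 stimuli from syngeneic culture had r = 0.719. Within numbers 1, 2 and 3 r was 0.971, 0.534 and 0.462, and without allogeneic replicate 1 it was 0.354 in the pooled data. Both comparisons use the same 3 syngeneic arrays, and 100 simulations of unchanged groups against shared controls gave a mean r of 0.501 (0.482 to 0.526). Exchanges of the arrays inside their numbers, which keep the pairing, gave a median r of 0.502 and a wider range (0.0455 to 0.817), with 15 of 108 as high as the real r. The covariance was 0.0926 against 0.0309 simulated, a difference of 0.0617. The 3 controls cannot be split into parts of 2, so part of this difference may come from them. Part may also come from the nearly identical allogeneic and anti-CD3/CD28 arrays numbered 1, where r was 0.971.

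Wapl, which releases cohesin from chromosomes, and Synj1, a phosphoinositide phosphatase of endocytosis, are remembered as genes the study's own publication drew from these samples, so their values here are not independent evidence. Wapl stood at 8.34 ± 0.82 (SD, n = 3) after allogeneic, 8.70 ± 0.54 after syngeneic and 8.42 ± 0.72 after anti-CD3/CD28 culture. Its allogeneic difference from syngeneic culture was −1.08 in number 1 and 0.00 in numbers 2 and 3, and 3 of its 5 probe sets shared the sign. Exactly equal values were common within a number, so 0.00 need not be a measured lack of change. Synj1 stood at 9.002 ± 0.50, 9.58 ± 0.67 and 8.88 ± 0.28, with allogeneic differences from syngeneic culture of −1.10, −0.26 and −0.39. Neither gene was called in any comparison (adjusted p = 1 in limma). H2-Ea encodes a class II chain that BALB/c cells make and C57BL/6 cells lack. Its brightest probe set stood at 4.55, 7.16 and 9.57 on the allogeneic arrays, at 4.49, 6.64 and 4.00 on the syngeneic arrays and at 4.55, 6.57 and 4.10 on the anti-CD3/CD28 arrays. A second probe set of H2-Ea, picked after its values were seen, stood at 4.67, 5.72 and 9.88 on the allogeneic, 3.93, 7.87 and 3.69 on the syngeneic and 5.02, 3.98 and 3.44 on the anti-CD3/CD28 arrays. The remaining one stood at 3.11 on all 3 arrays numbered 3 and between 3.07 and 4.29 on the others. Within number 3 the allogeneic array was highest on the first 2 of these probe sets and equal to the others on the last. In numbers 1 and 2 no probe set of H2-Ea puts the allogeneic array above the others by as much, so there the allogeneic group rests on the labels alone. Whether BALB/c cells were carried over into allogeneic replicate 3, without which the cytokine and dendritic cell calls against anti-CD3/CD28 ended, was not tested.

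**Figure D3:**
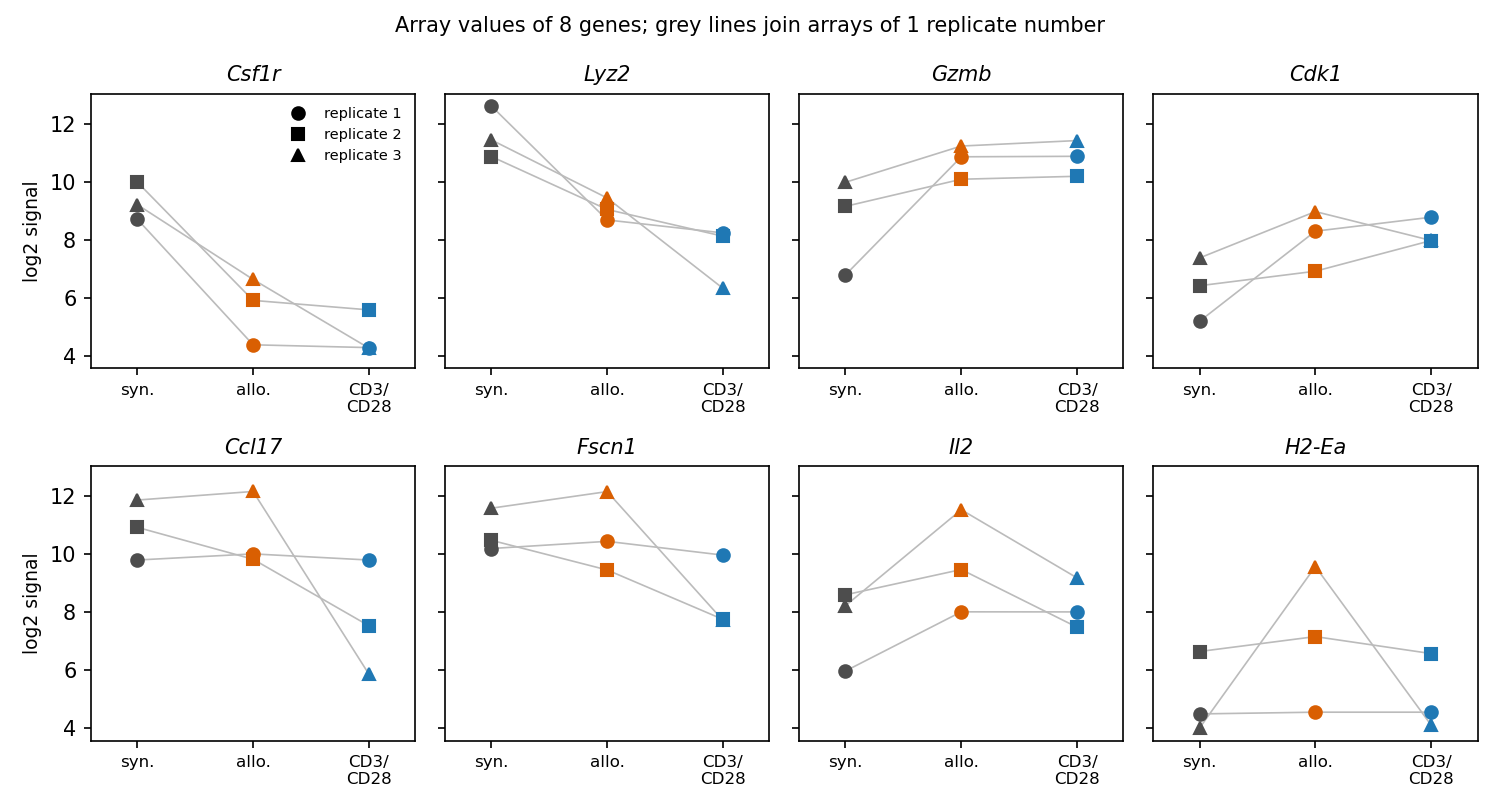
Log2 array signal (y axis) of single genes on each of the 9 arrays, by group (x axis), with marker shape for the replicate number and grey lines between arrays of 1 number. Csf1r and Lyz2 are lower on all stimulated arrays than on the syngeneic arrays, and H2-Ea stands at 9.57 on allogeneic replicate 3.

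Of the 34 lists, 12 were called in no comparison. Among them the microRNA pathway genes, which include the AGO genes, had a smallest adjusted p of 0.280 and the phosphoinositide phosphatases, which include Synj1, 0.382. The others were regulatory T cell genes (0.0884), erythroid genes (0.200), the unfolded protein response (0.306), cholesterol synthesis (0.314), stroma and endothelium (0.324), reported miR-150 targets (0.408), heat shock proteins (0.784), natural killer cells (0.874), reported miR-181a targets (0.874) and the type 1 helper programme (0.916). With the replicate block the smallest adjusted p of stroma and endothelium in camera was 0.0509. Its genes Col1a1, Col1a2, Col3a1 and Sparc stood at 7.67 or higher on all arrays numbered 2, and at 4.59 or lower on the others. No list member other than the 3 macrophage genes named above was called in any comparison when adjusted over the list alone without the block.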

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

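Alternatives chosen after the data were seen were those without the arrays numbered 1, the replicate block with dim genes left out, with an estimated correlation or with single arrays left out, and replicate number as a random block. Counts of called genes in limma were 0 in all 3 comparisons, and for genes that set allogeneic culture apart, in every fit that left out 1 array, with and without the block. Exceptions among the other alternatives were 1 gene for anti-CD3/CD28 against syngeneic with arrays centred on their medians (smallest adjusted p 0.0485), and, with replicate number as a random block, 1 gene for allogeneic (Csf1r, adjusted p = 0.0143) and 30 genes for anti-CD3/CD28 against syngeneic (smallest adjusted p 0.00146, 2 of them higher, Nop58 and Umps). The random block uses a consensus correlation of 0.932. With every probe set tested, 0 of 45037 were called, and 42, 253 and 48 had an unadjusted p under 0.05. Over 6582 refits of single genes, 7 passed the threshold. These are genes the fixed rule named, each in its own comparison, with list members taken from called lists only.

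Counts of called lists, 12, 17 and 17 in the 3 comparisons, depended on the test. With an estimated correlation they were 1, 1 and 0, and with the replicate block as well 0, 0 and 0. The replicate block gave 10 lists for allogeneic against anti-CD3/CD28, and quantile normalization gave 6 for allogeneic against syngeneic. Without the arrays numbered 1 the latter comparison had 6, and with the block and dim genes left out anti-CD3/CD28 against syngeneic had 11. The cause of these differences was not tested. Fits that left out 1 array, with and without the block, gave 6 to 17, 10 to 19 and 8 to 23 lists, and r between 0.354 (without allogeneic replicate 1) and 0.871 (without syngeneic replicate 1).

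Some called lists turned in camera's direction in a fit that left out 1 array, whether or not they were still called there. That direction rests on test statistics, so a list can turn while its shift keeps its sign. The ranges of their shifts follow, and their causes were not tested. For allogeneic against syngeneic culture they were −0.17 to 0.81 for cytokines and cytotoxic effectors, −0.27 to 0.47 for cytosolic ribosomal proteins, −0.67 to 0.11 for dendritic cell genes, −0.49 to 0.10 for the interferon response, −0.48 to 0.12 for quiescence, −0.67 to 0.017 for miR-155 targets and −0.22 to 0.53 for T cell activation. T cell activation also turned to −0.042 without the arrays numbered 1, with and without the block. For anti-CD3/CD28 against syngeneic culture they were 0.048 to 0.46 for cohesin, −0.18 to 0.55 for cytosolic ribosomal proteins, −0.031 to 0.59 for T cell activation and −0.14 to 0.64 for T cell identity. For allogeneic against anti-CD3/CD28 they were −0.092 to 0.44 for apoptosis regulators, −0.51 to −0.017 for cohesin, −0.046 to 0.87 for cytokines, 0.10 to 0.81 for dendritic cell genes, −0.57 to 0.19 for DNA replication, −0.52 to 0.23 for glycolysis and −0.61 to 0.28 for mitosis. In the same comparison they were −0.46 to 0.28 for oxidative phosphorylation, −0.037 to 0.41 for p53, −0.23 to 0.79 for miR-146a targets, −0.058 to 0.46 for miR-17 cluster targets, −0.53 to 0.23 for ribosome biogenesis and −0.60 to 0.16 for T cell identity.

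Array signal over background was not measured apart from RMA, so genes near the floor were judged only by leaving out dim genes, which kept 12564 genes and gave 0 called genes and 8, 15 and 15 lists.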

Other observations

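Tests chosen only after their result was seen were the splits for the counts of called genes and for genes that set allogeneic culture apart, the comparison of sorted values between numbers, the ratio of SDs and the ratio over 22 genes in number 1, both tests on macrophage markers, and the exchange of arrays inside numbers. Every hypothesis below was found and tested on the same 9 arrays.

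Other splits of the arrays were tried for each count. For called genes in limma all 10 of 10 splits of the 6 arrays of a comparison gave 0, as did the real one, in each of the 3 comparisons (unadjusted 27, 156 and 24 in the real splits), and 10 splits are too few for a share under 0.05. For called lists, 6, 2 and 3 of 10 splits gave as many as the real 12, 17 and 17, the highest others gave 22, 21 and 21, and again 10 splits are too few. Among splits that also part all 3 numbered pairs, the others gave 8, 13 and 9, then 14, 10 and 14, then 14, 15 and 12 lists. For genes that set 1 group apart from both others, all 100 of 100 splits of the 9 arrays gave at least the real 0. No count can be lower, so that outcome was fixed in advance and decides nothing, as for called genes above. The highest other split gave 5465 genes, which points to the replicate numbers as a structure of the arrays. An r of 0.719 or higher came up in 49 of 100 splits, the highest other at 0.925, but these splits mix the numbers. Exchanging arrays inside their numbers, which keeps the pairing, gave an r as high in 15 of 108 arrangements, the highest other at 0.817, so chance is not excluded for r.

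The first pattern is that arrays of 1 replicate number shared most of their variance, 85.3%. Sorted values differed by at least 0.971 (log2) between numbers and at most 0.384 within them, and exactly equal values occurred only within numbers. These values argue against 1 joint normalization of all 9 arrays. Separate normalization of the 3 arrays of each number may thus contribute to the shared variance. For the stromal genes below, their values argue against separate normalization as the whole cause. For the other genes that is open, since 76.2% of the variance lay between numbers after quantile normalization. The bound set beforehand, a share above 1 in 2 of the deposited one, was met, but it was a wrong bound, because quantile normalization of summarised values leaves the probe set effects fitted in each run as they were. Stromal genes were looked up after the data were seen. Col1a2 stood at 11.3, 9.23 and 8.79 on the syngeneic, allogeneic and anti-CD3/CD28 arrays numbered 2, and at 4.00 to 4.37 on the others. Col3a1 stood at 10.9, 9.27 and 8.55 against 3.12 to 4.25, and Sparc at 10.8, 9.65 and 8.98 against 4.37 to 4.49. Sorted values differed by at most 2.10 between numbers, so these gaps exceed what differing array scales give. No biological explanation was tested, and differences between cultures, days or amplifications stay open.

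The second pattern is that the allogeneic and anti-CD3/CD28 arrays numbered 1 were nearly alike. Compressed values in number 1 are argued against by the ratio of the SD of their difference to that of allogeneic minus syngeneic, 0.245 in number 1 against 0.935 and 1.45 in numbers 2 and 3. What stays open is 1 RNA, or a mixture of both, on the 2 arrays, a wrong label on 1 of them, which was not tested, and, as the biological explanation, the same effect of the 2 stimuli in that culture. Over 22 genes lower in anti-CD3/CD28 than in both co-cultures in numbers 2 and 3, the allogeneic difference over the syngeneic one was 0.0733 in number 1, but this restates how alike the 2 arrays are and decides nothing, as did an earlier test on the same genes. The difference between the 2 stimuli had r = 0.0409 between numbers 2 and 3, which noise alone or a difference that varies by culture would both give, and the 3 explanations cannot be told apart.

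The third pattern is that macrophage and monocyte genes were lower in both stimulated groups, Csf1r, Lyz1 and Lyz2 among them. The macrophage list lay 1.04 below the dendritic cell list (−1.04, SD 0.231 over 3 numbers) in allogeneic against syngeneic culture. Equal loss of every myeloid kind would give equal falls only if both lists followed cell numbers alike, which was not measured. The gap thus cannot decide against fewer carried-over cells of every myeloid kind. Fewer macrophages or monocytes among the purified cells could explain all 15 of 15 list members being lower in both groups, but a change of AGO-bound RNA within such cells cannot be told apart from it without counts of these cells or input RNA. The 15 macrophage genes share 0 members with the other lists. The miR-155 targets without Spi1 and Cebpb (8 genes) had adjusted p = 0.0258, 0.0395 and 0.950 in the 3 comparisons in camera with the preset correlation. No estimated correlation was tried for these 8 genes, and with one the full list lost its calls. Spi1 stood at 5.25, 5.53 and 7.33 on the allogeneic and 5.25, 5.47 and 6.64 on the syngeneic arrays, so leaving it out removed no fall there. Whether the 8 genes, Maf among them, are free of signal from myeloid cells was not tested.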
